A study of Oryzias latipes with 6 samples.

How the data were processed

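RNA was profiled from 6 pools of medaka (Oryzias latipes) embryos of the Cab strain at stage 40 of the Iwamatsu series, 3 pools of wild type embryos and 3 pools of embryos knocked out for SEDL. Per the labels' protocols, libraries were prepared with TruSeq RNA reagents from 500 ng of total RNA per sample. The labels call the pools biological replicates. How many embryos a pool held, and whether the pools came from separate clutches, is not given in the sources used here. The p-values therefore measure the spread between these pools.

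The deposited table holds raw read counts per Ensembl gene ID, whole numbers with no normalization, in 1 column per library. Per the submitters' processing notes the aligner was STAR, with no version, and the genome build named there is mm10, a mouse build. Every gene ID in the table belongs to the medaka Ensembl series, so the build behind the counts is not established and no coordinates are given. The counting tool, the annotation release, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Paralogs or overlapping genes that share reads could therefore not be marked as such. Each column carries a library code that is also in the description of 1 sample, which assigned columns to samples. The table has 0 further columns of sample values. It names no rows other than gene IDs.

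The table does not pair its IDs with gene symbols, and the RefSeq gene table of assembly ASM223467v1 used for names carries no Ensembl IDs for this organism. Of 20459 gene IDs, 0 matched a symbol. Gene lists that had been fixed before the data were examined, covering trafficking complexes, matrix and skeletal genes, stress responses and markers of tissues, could not be matched to the IDs, so no list was tested. For the same reason the knocked-out gene could not be located in the table, and the genotype labels could not be checked against its level. The rule for named genes, also fixed in advance, then limits the text to the 2 higher and the 2 lower IDs with the smallest p. GC content and gene length were not analysed here.

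Differential expression was computed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 18011 of 20459 IDs. The tested genes held over 99.9% of the counts in each library. Library sizes were scaled with TMM factors. A quasi-likelihood model with robust estimation (glmQLFit, glmQLFTest) compared knockout with wild type without covariates, and Benjamini-Hochberg adjusted p under 0.05 was called. Fold changes are knockout minus wild type on the log2 scale. Standard errors were taken as the size of the log2 fold change divided by the square root of the test's F. Levels of single genes are given as CPM, the counts of a gene relative to the TMM-scaled size of its library. Log2 CPM for principal components and distances between libraries used a prior count of 2. Measures of whole libraries were compared by two-sided exact permutation tests, for which 3 against 3 cannot give a p below 0.1.

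The procedure was tested on simulated data, in 5 runs of 18011 genes with the means, dispersions and library sizes of these libraries and 200 genes changed per run. It called 16.7% of genes changed 1.5-fold, 74.9% of genes changed 2-fold and 97.6% of genes changed 4-fold. Of all simulated calls 9.50% were false, which is above the nominal 5%, on average 13.2 unchanged genes per run. The simulation held no deviations shared by same-numbered libraries. The p cutoff after adjustment is also stricter with 200 changed genes than with many. The simulated rates of detection and of false calls are therefore not the rates of the real comparison.

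Library totals ran from 18499107 to 23393540 counts. No 2 libraries of a group differed by as little as sampling noise. The chi-square statistic per degree of freedom was at least 17.3 in every pair within a group, where sampling noise alone gives about 1. This cannot tell separate pools from separate library preparations of 1 pool. Each library was counted as 1 replicate, since the labels call the pools biological replicates. Labels give the same replicate numbers in both groups. Deviations from the group means correlated across genes with r between 0.35 and 0.43 for same-numbered libraries and between -0.24 and -0.14 for the others, and each of the 6 libraries correlated best with its own number. Because deviations were taken from means of 3 libraries, positive values for same-numbered libraries push the others below 0. The negative values are therefore not separate evidence. With 3 libraries per group, a best match by number can also arise by chance, and this was not tested. The pairing comes from the numbers in the titles and this check, since no label says what a number marks.

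Alternatives were listed before the data were examined. They were RLE and upper quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, each library left out in turn, and other thresholds. Removing each library's trend against abundance by loess (span 0.3) and thinning every library to the lowest total were added after seeing the data. Classes of abundance and of fold size, and the definitions of genes near 0 in a group, were also set after seeing the data.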

Results

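The data set held 6 RNA-seq libraries from whole medaka embryos at stage 40 of the Iwamatsu series. There were 3 pools of wild type embryos and 3 pools of embryos knocked out for SEDL. SEDL is a former symbol of TRAPPC2, which encodes sedlin, a subunit of the TRAPP complexes that act in transport from the endoplasmic reticulum to the Golgi. Wild type replicates 1 to 3 held 22178480, 21530108 and 18499107 counts and knockout replicates 1 to 3 held 23393540, 20638891 and 18962836, so depth overlapped between the groups (exact permutation p = 0.9). Of 20459 gene IDs, 495 had no counts in any library and 18011 were tested. The table gives Ensembl IDs without symbols, so genes are described by ID, abundance and size of change, and the level of the knocked-out gene itself is not reported.

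The comparison asked how the embryonic transcriptome differs when SEDL is lost. Broad changes in both directions separated the groups. In the knockout, 2857 genes were higher and 3366 were lower than in wild type, together 34.6% of the genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). This fit did not use the replicate numbers, and with them as a block 4247 genes were higher and 4473 lower. In the fit without a block the median called increase was 1.62-fold and the median called decrease 1.87-fold. Genes that rose took 27.6% ± 1.75 of all counts in wild type and 40.3% ± 1.18 in the knockout (SD, n = 3 each). Genes that fell took 16.9% ± 1.88 of the counts in wild type and 7.65% ± 0.172 in the knockout (SD, n = 3 each). These genes were called on the same libraries, so their shares describe the size of the change and are not a separate test of it.

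Large decreases outnumbered large increases. Among called genes, 1477 fell by 2-fold or more and 691 rose by 2-fold or more. At 4-fold or more, 383 genes fell and 126 rose. Decreases of these sizes outnumbered increases under each other scaling tried and with each library left out. Over all tested genes, called or not, the 3 knockout values did not overlap the 3 wild type values in 49.0%. Chance gives 10% on average over all ways to split the libraries. Genes vary together, so the share for a single split can lie far from 10%, and the 49.0% is not a test.

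The separation was also visible in whole libraries. The first principal component of log2 CPM held 74.2% of the variance and placed the wild type libraries at -37.6, -51.9 and -62.0 and the knockout libraries between 45.3 and 53.2. The median absolute difference between libraries across genes was 0.21 to 0.25 on the log2 scale within wild type and 0.18 to 0.20 within the knockout. Between the groups it was 0.33 to 0.49. The second component held 9.78% of the variance and set replicate 2 of both groups apart from replicates 1 and 3.

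**Figure D1:**
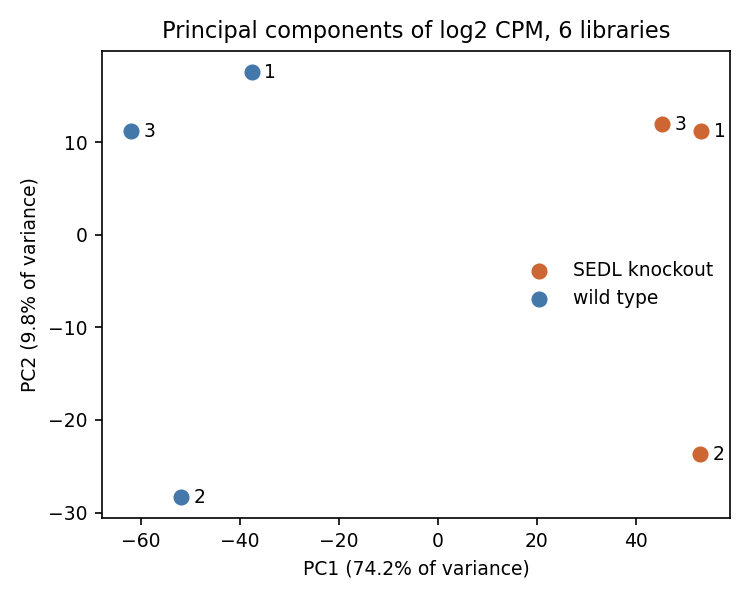
Principal components 1 (x axis, 74.2% of the variance) and 2 (y axis, 9.78% of the variance) of log2 CPM over the tested genes, in arbitrary units; each point is a library, coloured by group and marked with its replicate number. The 3 wild type libraries lie between -62.0 and -37.6 on the first component and the 3 knockout libraries between 45.3 and 53.2.

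**Figure D2:**
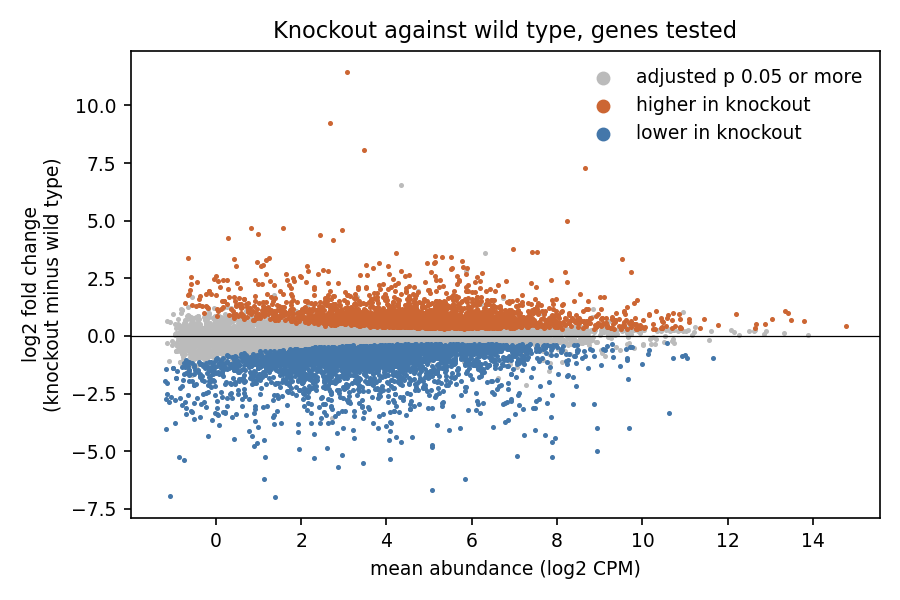
Log2 fold change (knockout minus wild type, y axis) against mean abundance (log2 CPM, x axis) for the 18011 genes tested; each point is a gene, coloured where the adjusted p was under 0.05. The 3366 decreases had a median of 1.87-fold and the 2857 increases a median of 1.62-fold, and with TMM scaling increases make up most calls at the high end of abundance.

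With TMM scaling, the most abundant transcripts of the embryo rose more often than they fell. Of the 10 most abundant genes, 7 were higher, 0 lower and 3 not called, with log2 fold changes from 0.06 to 1.07. By DESeq2 7 were higher and 0 lower, and at an unadjusted p under 0.05 in edgeR 0 were lower as well. Among the 100 most abundant genes, 43 were higher and 9 lower, and 67 and 12 with the replicate number as a block. Those 100 genes held 29.4% of wild type counts and 33.2% of knockout counts. The 10 top genes of each library took 10.9% ± 0.585 of the counts in wild type and 13.8% ± 0.489 in the knockout (SD, n = 3 each, exact permutation p = 0.1, the smallest that 3 against 3 allows). Without knockout replicate 1 the top 100 held 26 higher and 8 lower genes, and without knockout replicate 2 it held 24 and 8. Higher genes also outnumbered lower ones in the top 100 with RLE scaling (46 and 9) and upper quartile scaling (31 and 10). Offsets that subtract each library's trend against abundance, and with it such a lean by construction, left 20 higher and 19 lower in the top 100, and 5 higher and 1 lower in the top 10.

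With TMM scaling, scarce transcripts fell more often than they rose. Among 2324 genes with a mean of 1 to 4 CPM, 502 were lower and 177 higher. Among 5676 genes of 4 to 16 CPM, 1300 were lower and 623 higher, with 941 and 408 without knockout replicate 2 and 1695 and 938 with the replicate number as a block. Of 469 genes at 256 CPM or more, 172 were higher and 59 lower, and 108 and 47 without knockout replicate 2. The median log2 fold change of all genes in a class ran from -0.22 below 1 CPM to 0.25 at 256 CPM or more. Single-gene standard errors had a median of 0.39 in the lowest class and 0.13 in the highest, so small changes of scarce genes were less detectable. With each library's trend against abundance removed, the share of higher genes among calls was 35.9% below 1 CPM and 47.3% at 256 CPM or more, against 19.1% and 74.5% without that correction. Lower calls were then the majority in each of the 6 classes, with 89 higher and 99 lower at 256 CPM or more and 828 higher and 1013 lower at 4 to 16 CPM. The class medians under that correction were 0.05 below 1 CPM, 0.02 at 1 to 4 CPM and 0.01 at 256 CPM or more, which the correction centres near 0 by construction. The median at 1 to 4 CPM was -0.17 with RLE and -0.26 with upper quartile factors, against -0.19 with TMM. These factors shift all genes by nearly the same amount, 0.02 and -0.07 for the median gene. The sign of that median could therefore hardly change, and it is not separate support for the lean. Upper quartile scaling left higher genes the minority at 16 to 64 CPM, 1020 against 1301 lower, where TMM gave 1307 higher and 1069 lower. In that class 863 were higher and 760 lower without knockout replicate 2, and 1977 and 1506 with the replicate block. With every library thinned to the same total, genes with at least 10 counts numbered 17947 ± 28.2 in wild type and 17673 ± 74.2 in the knockout (SD, n = 3 each, exact permutation p = 0.1, the smallest possible).

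**Figure D3:**
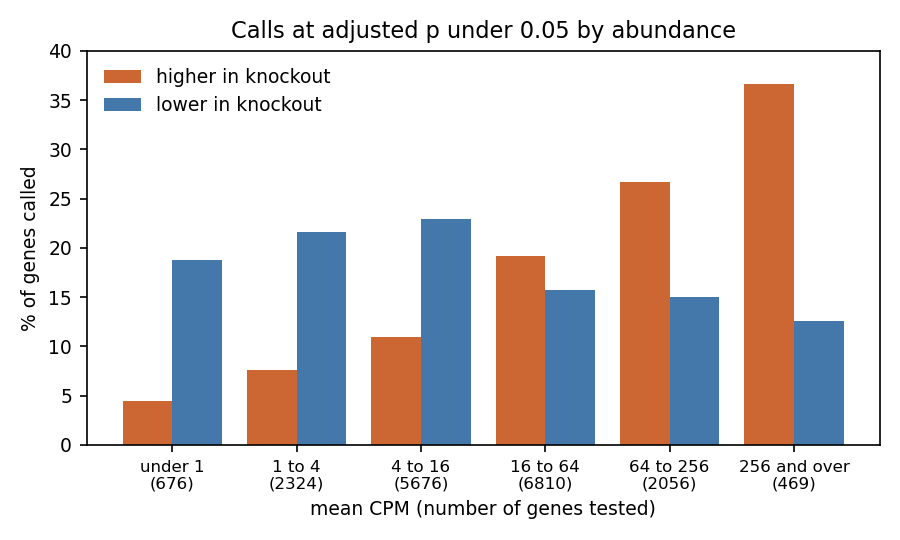
Share of tested genes called higher or lower in the knockout (y axis, % of the genes in the class) in 6 classes of mean CPM (x axis, with the number of genes). With TMM scaling, calls of higher genes rise from 4.44% to 36.7% across the classes, while calls of lower genes are between 12.6% and 22.9%.

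The strongest evidence for an increase was for ENSORLG00000017377, at 5.17 ± 1.23 CPM in wild type and 804 ± 204 CPM in the knockout (SD, n = 3 each). Its log2 fold change was 7.28 with a standard error of 0.27, and its adjusted p by edgeR was 1.41e-06. In raw counts it had 92 to 127 per wild type library and 13317 to 19253 per knockout library. ENSORLG00000003399 rose from 18.3 ± 3.14 to 586 ± 132 CPM, a 32.1-fold increase with a standard error of 0.21 on the log2 scale (edgeR adjusted p = 1.58e-06). On the other side, ENSORLG00000010599 fell from 2880 ± 382 to 285 ± 25.6 CPM, a log2 fold change of -3.33 with a standard error of 0.13 (edgeR adjusted p = 1.41e-06). ENSORLG00000016370 fell from 17.3 ± 1.65 to 1.02 ± 0.0413 CPM, a log2 fold change of -4.07 with a standard error of 0.18 (edgeR adjusted p = 1.90e-06). All 4 kept their direction and their call in each of the 15 alternative settings in which they were refitted. They had been picked by smallest p in these same libraries, so this persistence is not separate support.

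**Figure D4:**
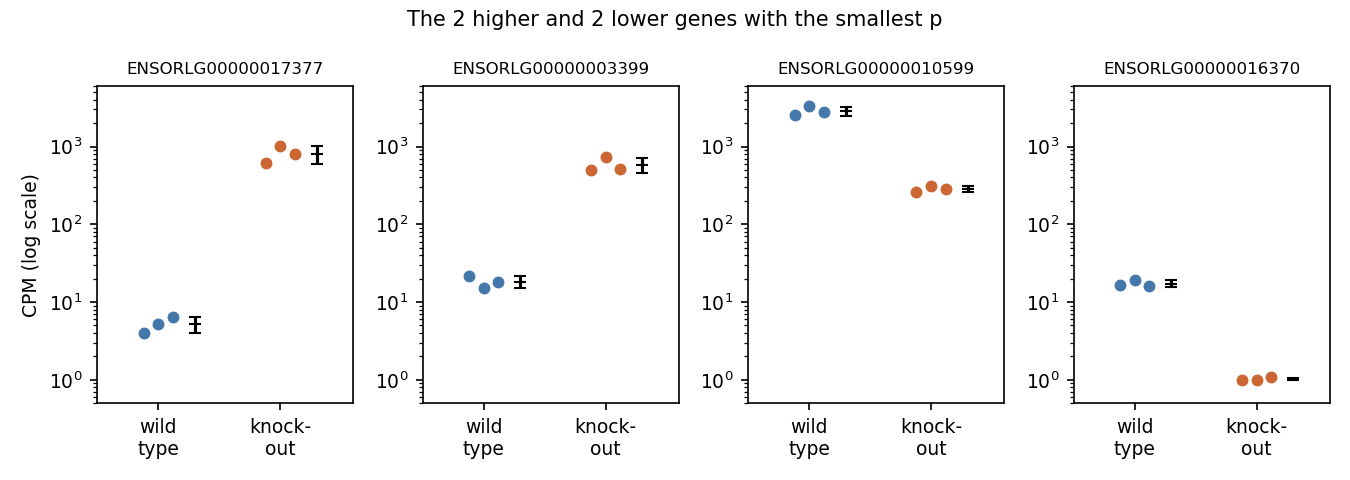
CPM on a log axis (y) in the 3 wild type and 3 knockout libraries (x) for the 2 higher and 2 lower genes with the smallest p; coloured points are libraries, and black marks are the mean ± SD of 3. In each gene all 3 knockout libraries lie on one side of all 3 wild type libraries.

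A few genes were close to switched on or off. With 3 counts or fewer over all 3 libraries of a group taken as near 0, and at least 10 counts in every library of the other group, 2 genes were near 0 in wild type and 7 near 0 in the knockout. All 9 were among the called genes. The 7 genes near 0 in the knockout had 11 to 158 counts per wild type library. A separate definition by ratio asked for every library of one group to hold at least 20 times the highest count of the other group plus 1. It gave 4 genes above wild type, of which 2 were also near 0 in wild type, and 7 below it, of which 1 was also near 0 in the knockout. The ratio does not ask for a level near 0. Genes it picked had up to 127 counts in a wild type library and up to 399 in a knockout library on their low side.

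Genes that fell were not even across the wild type pools. Among 58 called genes at least 16-fold lower in the knockout than in wild type replicates 2 and 3, wild type replicate 1 was at a median of 0.497 of the mean of those 2 replicates and below both of them in 86.2% of the genes. Among 2264 called genes lower by 1.5- to 4-fold it was at a median of 0.843 of that mean and below both in 60.2%. Among 15 called genes at least 16-fold higher in the knockout, wild type replicate 1 was at a median of 1.62 times that mean. Leaving out wild type replicate 1 gave 2505 higher and 3194 lower genes. In the simulated comparison described with the methods, 9.50% of calls were false, above the nominal 5%, with 200 changed genes per run. Neither this rate nor the rates of detection were simulated with as many changed genes as were called here. Deviations shared by same-numbered libraries were not simulated either.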

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

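Both counts stayed within 1.5 times their value, 2857 higher and 3366 lower, under each scaling, filter, tool and left-out library tried. Only the threshold moved them further: 1487 genes were higher and 1906 lower at adjusted p under 0.01, by construction of the threshold. DESeq2 gave 3074 and 3250, with the adjusted p of 880 genes undefined, and limma-voom gave 2856 and 3279. Leaving out 1 library gave 1914 to 2660 higher and 2486 to 3194 lower genes. With the replicate number as a block, for which the pairing check is given with the methods, 4247 genes were higher and 4473 lower. Of the 6223 calls, 6204 were shared with that blocked fit, and it changed no call or direction of the 4 genes named. Upper quartile scaling lowered the share of higher genes among calls from 45.9% to 36.9%, with 2303 higher and 3937 lower, and shifted the median gene by -0.07 on the log2 scale. No called gene shared with an alternative had the opposite direction. Fits to the same or nearly the same counts could hardly give one, so this is not separate support. Thinning every library to the lowest total gave 2808 higher and 3312 lower genes. The median standard error was 0.39 below 1 CPM and 0.13 at 256 CPM or more, and how much of that difference is due to depth was not tested. No value was obtained for the knocked-out gene or for any gene list, since IDs could not be paired with symbols, so the alternatives listed for these were not run.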

Other observations

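The tests by thinning and by removal of the abundance trend, and those of library slopes, of differences between replicates and of mixed RNA, were chosen only after the results they bear on had been seen.

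Of the genes counted in the results as near 0 in wild type or at least 20 times above it, 3 were at 0 to 5 counts in each wild type library and present in every knockout library, but at uneven levels. Their counts in knockout replicates 1, 2 and 3 were 49, 136 and 550 for the first, 85, 353 and 525 for the second and 144, 371 and 758 for the third. Scaled to library totals, the highest knockout library exceeded the lowest by 13.8, 7.62 and 6.49 times. All 3 ordered the knockout libraries alike, and their edgeR adjusted p were 0.0207, 0.0407 and 0.00492. They were picked after their values were seen.

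The breadth of the difference, 6223 of 18011 tested genes, was compared with other ways to divide the 6 libraries. Only 1 of the 10 splits, the real one, called as many genes, and the highest of the other 9 called 0, both among the 3 other splits that part every same-numbered pair and among the 6 that do not. By limma-voom these 9 splits also called 0 genes, and at an unadjusted p under 0.05 in edgeR they gave 48 to 603 genes against 8084. With 10 splits the share cannot fall under 0.05. Each of the other 9 puts wild type and knockout libraries on both sides, so the difference between the groups widens the spread within each side. Their 0 calls therefore give no background rate for the 6223. A difference in depth is argued against as the cause, since library totals overlapped between the groups. Thinning every library to the lowest total, which could change little for that reason, left 6120 calls. A trend of each library against abundance is argued against as the whole cause, since 5880 genes were called with that trend removed, of which 5233 were among the original calls. What stays open is whether the breadth follows from the knockout itself or from other differences between the pools, such as clutch, genetic background or exact developmental time, which no label separates from genotype.

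Calls leaned towards increases among abundant genes and decreases among scarce ones. The slope of a library's log2 level on mean log2 CPM was 0.0164 to 0.0462 in the knockout and -0.0457 to -0.0231 in wild type. Depth is argued against, since library totals overlapped between the groups, so that thinning could change little. The difference of the groups' mean slopes was 0.0701 as deposited and 0.0695 after thinning. A trend of single libraries unrelated to genotype cannot be told apart from a group effect. The gap of 0.0395 between the groups was wider than the widest range within a group, 0.0298, but 3 libraries against 3 separate this way by chance with an exact permutation p of 0.1. That test does not use the replicate numbers as pairs, and no paired test was run. For replicates 1, 2 and 3 the slopes were -0.0231, -0.0365 and -0.0457 in wild type and 0.0427, 0.0462 and 0.0164 in the knockout.

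By rank correlation across genes, wild type replicate 1 was closer to each knockout library (0.937 to 0.946) than replicate 2 (0.927 to 0.932) or replicate 3 (0.907 to 0.921), while by the median absolute log2 difference it overlapped with replicate 2 (0.33 to 0.39 against 0.35 to 0.37). Its difference from replicate 3 correlated across genes, which are not independent replicates, with knockout 2 minus wild type 2 at a Spearman rho of 0.31 and a Pearson r of 0.36, and its difference from replicate 2 with knockout 3 minus wild type 3 at a rho of 0.13 and an r of 0.22. The 4 other differences, which do not contain wild type replicate 1, had rho from -0.08 to 0.21 and r from 0.01 to 0.15. Among them, wild type 2 minus 3 and knockout 2 minus 3 were set against knockout 1 minus wild type 1, with rho of 0.19 and 0.21. Both of these contain wild type 1 on that other side, so they give no background free of it. Knockout 1 minus 3 and knockout 1 minus 2, which were set against pairs without it, had rho of 0.125 and -0.077. Whether the 0.13 is particular to wild type replicate 1 can therefore not be told. By rho only the 0.31 lay above all 4 other differences, while by r the 0.22 did so too. A trend with abundance and a difference in depth are argued against, since the rho of 0.31 was 0.29 with the trend removed and 0.30 after thinning. Knockout RNA mixed into this library would give 1 share for all genes. Genes at least 16-fold higher in the knockout put the knockout share in wild type 1 at a median of 2.16% (95% interval -0.507% to 9.29%, 15 genes), while genes at least 16-fold lower put it at 52.3% (44.7% to 60.2%, 58 genes). Both sets were called in a fit that included wild type 1, so higher genes with a large share in it could miss the call. The contrast may therefore be partly set by that choice. In wild type 1 these 15 genes were at a median of 1.62 times the mean of wild type replicates 2 and 3. A common share near 52.3% is still argued against, since it would have raised them far more. The intervals treat the genes of 1 library as independent and do not measure spread between pools.

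For genes at least 16-fold lower, the same share computed for wild type replicates 2 and 3 was -15.1% (95% interval -46.9% to 10.1%, 38 genes) and -10.1% (-21.8% to 1.43%, 44 genes), both intervals including 0. Here too the intervals treat genes as independent, so they are not tests of 1 pool against another. Genes lower by 1.5- to 4-fold put it at 32.7% for replicate 1 (30.7% to 34.3%), 1.59% for replicate 2 (-0.963% to 4.12%) and -22.4% for replicate 3 (-24.5% to -19.4%). Genes higher by 1.5- to 4-fold did not set replicate 1 apart, with medians of 8.30%, 9.96% and -5.66% for replicates 1, 2 and 3. The share is scaled by the gap between the groups, so 52.3% and 2.16% do not compare unevenness between pools. Genes at least 16-fold higher were at a median of 1.62, 0.995 and 0.582 of the other wild type replicates in replicates 1, 2 and 3 (15, 9 and 10 genes). A hypothesis is that some strongly changed transcripts belong to a programme or tissue that also varies between wild type pools. Such variation may reflect developmental timing within stage 40 or the make-up of a pool. The hypothesis was not tested, since markers could not be matched to the gene IDs. If it holds, some of the strong changes would not depend on the genotype alone.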
